A study of Mus musculus with 8 samples.

How the data were processed

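Total RNA from the colon of male mice on a C57BL/6 background was labelled with Cy3 or Cy5 and hybridised in pairs to 4 arrays, per the labels' protocols. There were 8 samples, 4 of each genotype. Arrays were read with Agilent Feature Extraction 9.5.1, per the submitters' processing notes. The sample titles carry a different number for each sample, and nothing else states that the samples are separate animals. The p-values measure the spread between these samples.

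The authors deposited single-channel log2 intensities, 1 column per sample. Per the deposited readme, spots flagged as non-uniform outliers were set to missing, and intensities were background corrected by Edwards' method with an offset of 30. Dye bias was reduced by loess within arrays, and arrays were normalised to each other by Aquantile. Probes with more than 30% missing values were removed and the remaining gaps were imputed from nearest neighbours. Which values were imputed is not recorded in the tables, and an imputed value carries less independent information than a measured one. The offset compresses differences between dim probes. The values ran from 4.40 to 18.8, and the log2 of the offset is 4.91. Flags for spots above background or saturated were not used here, so no probe could be called undetected.

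The full matrix had 43379 rows for 41174 distinct probes. Each of 245 probes was listed in 10 rows with identical values (largest range 0), and these were counted once. Repeat spots therefore gave no measure of technical error. The series value table held 40928 of the probes with the same values (largest difference 0) and was used as an alternative. Probe identifiers were matched against a table of RefSeq genes (GRCm38.p6), in which 0 rows held an Agilent probe identifier, so no probe was given a gene name or position. The test of Runx1, the tests of gene lists (limma's camera and fry) and the choice of 1 probe per gene were planned and not run for that reason.

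The knockout minus wild-type difference of each probe was estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 samples, with dye as a covariate. The array, which holds 1 sample of each genotype, entered as a random block through duplicateCorrelation with statmod 1.5.0. The estimated correlation within arrays was 0.108. The fit had 5 residual and 3.41 prior degrees of freedom. All probes were tested, with no filter on dim probes. A probe was called at a Benjamini-Hochberg adjusted p under 0.05. A fold is the power of 2 of the log2 difference. The authors' own model, per the deposited readme, used the correlation within spots (intraspotCorrelation) and named no dye term, and it was run as an alternative.

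Deviations from the group means of the 2 samples on an array correlated at -0.10, 0.24, 0.00445 and -0.20 on arrays 1 to 4. The replicate numbers used here follow the order of deposition, so that the 2 samples with the same number share an array, and they mark no common animal.

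The design, the alternatives and the rule for naming probes were fixed before the data were examined. The rule named the 12 largest changes in each direction among probes past the threshold, above the 25th percentile of mean intensity and with the same sign on all arrays, filled up by the smallest p-value. Because the identifiers carry no gene names, it was limited to 2 probes in each direction. The alternatives covered quantile normalisation, median centring, array as a fixed block or ignored, no dye term, age as a covariate, filters on dim probes, trended and robust moderation, the series value table, and leaving out each sample or each array.

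The fit was tested on simulated data with the real probe means and 200 changed probes among 41174. Variances were drawn from the distribution that limma fitted over all probes. The simulated probes were independent, and no sample stood apart. More changed probes than were called in the data ease the adjusted threshold, so the recovery may be too high for these data. It recovered 50% of the probes changed by 1 on the log2 scale, 98% of those changed by 2, 98% of those changed by 3 and 100% of those changed by 4. It called 12 unchanged probes in that simulation and 0 when nothing was changed. For each of the 35 splits of the samples into groups of 4, the probes with no overlap between the groups were counted. The fit itself was repeated for the 34 splits that differ from the dyes, with the correlation within arrays estimated on 10000 randomly drawn probes. Figures were drawn with matplotlib 3.10.9.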

Results

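Gene expression was measured in whole colon from male mice whose Runx1 gene was flanked by recombination sites (floxed). Runx1 encodes a DNA-binding transcription factor best known from blood cell development. The knockout mice carried a Cre recombinase driven by the Villin promoter, which is active in the epithelium of the gut, and the wild-type mice had the floxed gene without the recombinase. The study asked how loss of Runx1 from the epithelium alters the colon transcriptome. There were 4 knockout and 4 wild-type samples, hybridised to 4 two-colour Agilent arrays. Each array held 1 knockout and 1 wild-type sample, with the knockout in Cy3 on arrays 1 and 3 and in Cy5 on arrays 2 and 4. The knockout mice were 101, 101, 81 and 63 days old on arrays 1 to 4, and the wild-type mice were 88, 88, 82 and 63 days old. The table gave a log2 intensity for 41174 probes in every sample. The median probe had a log2 intensity between 6.39 and 6.44 in each of the 8 samples. Precision was limited by the number of arrays, and the median standard error of a knockout minus wild-type difference was 0.16 on the log2 scale. The probes carried Agilent identifiers without gene names, so the genes behind them, Runx1 itself and gene groups were not analysed here.

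No separation of the genotypes across all probes was detected. After the mean of each probe was subtracted, the mean correlation between 2 samples was -0.097 within a genotype and -0.14 between genotypes. Of the 35 ways to split the samples into groups of 4, 10 gave a difference between these means at least as large as the genotypes did, the genotypes included (exact permutation test, one-sided, p = 0.286). Without wild-type replicate 1 the means were -0.12 and -0.19, and 9 of 35 splits gave a difference as large (exact permutation test, one-sided, p = 0.257). Most splits in both tests ignored the pairing of the samples on arrays, so neither p-value takes that pairing into account. Wild-type replicate 1 stood furthest from the rest, with correlations of the uncentred intensities of 0.955 to 0.967 with the other samples. In that sample 4263 probes, or 10.4%, differed more than 2-fold from the median of the other 7 samples. The corresponding numbers were 282, 477 and 703 probes in wild-type replicates 2, 3 and 4, and 254, 121, 606 and 970 probes in knockout replicates 1 to 4.

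**Figure D1:**
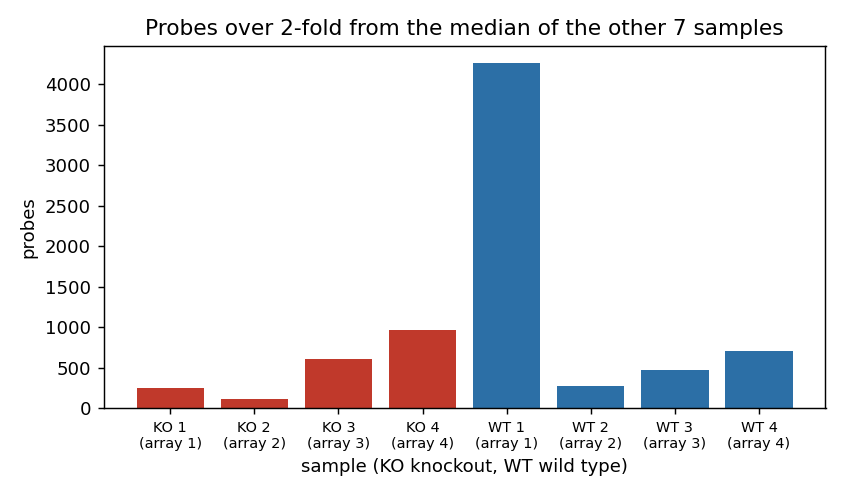
Number of probes (y axis) whose log2 intensity lay more than 2-fold from the median of the other 7 samples, for each sample (x axis; red, knockout; blue, wild type). Wild-type replicate 1 reached 4263 probes, against 121 to 970 in the other samples.

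A small set of probes differed strongly between the genotypes in the fit over all 8 samples, nearly all of them higher in the knockout colon. With limma's moderated test and Benjamini-Hochberg adjustment over 41174 probes, 11 probes were higher and 1 was lower in the knockout at an adjusted p under 0.05. No probe was called with the array as a fixed block, without knockout replicate 1 or without array 4. The 11 rises ranged from 1.91-fold to 54.1-fold with a median of 4.09-fold. They exceeded 4-fold for 6 probes and 16-fold for 3. On all 12 called probes the 4 knockout samples lay entirely on one side of the 4 wild-type samples. The sign of the difference was therefore the same on each of the 4 arrays, which adds no separate support. Choosing probes at this threshold itself favours such separation.

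The largest rise was measured by probe A_51_P334930. Its log2 intensity was 17.8 ± 0.62 (SD, n = 4) in the knockout and 12.1 ± 0.78 (SD, n = 4) in the wild type. The difference was 5.76 on the log2 scale, with a standard error of 0.39 and an adjusted p of 0.00543 in limma. On the single arrays the difference lay between 3.98 and 6.86. Flags for saturated spots were not used, so whether the bright knockout signal of this probe was saturated was not examined. Probe A_51_P314669 had the second largest rise, from 7.94 ± 0.95 to 13.2 ± 0.42 (SD, n = 4 each). This is a difference of 5.22 with a standard error of 0.39 (limma adjusted p = 0.00808), or 37.2-fold. Both rises lost their call with the array as a fixed block (limma adjusted p = 0.98 for each with a dye term and 0.515 without), without knockout replicate 1 (limma adjusted p = 0.105 and 0.26) and without arrays 1, 3 or 4. The second was also lost without knockout replicate 4 (limma adjusted p = 0.133) and with age as a covariate (limma adjusted p = 0.0667). In the fits that ended a call the estimate was 5.12 to 6.06 for the first probe and 4.68 to 5.31 for the second. Over 27 alternatives the adjusted p ranged from 0.000224 to 0.98 for the first and from 0.000482 to 0.98 for the second. The knockout values of probe A_51_P314669, 12.6 to 13.5, were separated from the wild-type values, 6.61 to 8.64, by more than either group's spread.

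The single probe called lower was A_52_P422494, at 8.91 ± 0.77 in the wild type and 6.90 ± 0.60 in the knockout (SD, n = 4 each). The log2 difference was -2.02 with a standard error of 0.22 (limma adjusted p = 0.0453). It was uneven across arrays, from -3.28 on array 1 to -0.36 on array 4. When 1 sample was left out, this call held only without wild-type replicate 1 or 3. It was lost with no dye term (limma adjusted p = 0.522), with the array as a fixed block (0.98 with a dye term and 1 without), with no block (0.0666), with age as a covariate (0.157) and without any one of the arrays (0.168 to 0.253). Over 27 alternatives its estimate lay between -2.325 and -1.705, and its adjusted p between 0.00475 and 1. Probe A_51_P307150, the next lower probe by p-value, did not pass the threshold (limma adjusted p = 0.144). Its mean was 10.1 ± 0.08 in the wild type and 7.68 ± 0.96 in the knockout (SD, n = 4 each), with knockout replicate 4 at 9.08 and the other knockout samples at 7.02 to 7.53.

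**Figure D2:**
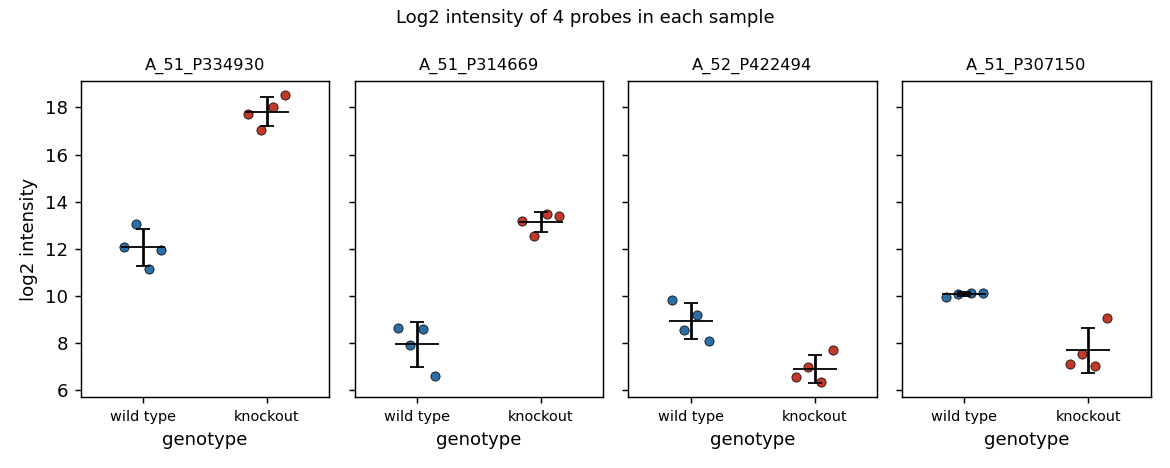
Log2 intensity (y axis) of 4 probes in each wild-type (blue) and knockout (red) sample; horizontal lines are means and error bars the SD of 4 samples. The genotypes do not overlap on any of the 4 probes, and A_51_P334930 rises from 12.1 to 17.8.

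The called probes lay at different levels of intensity, which are not comparable between probes as transcript abundance. Of the 11 higher probes, 7 lay above the 75th percentile of all probes by mean intensity, 3 between the 50th and 75th, 1 between the 25th and 50th and 0 below the 25th. This mean covers both genotypes, so a rise in the knockout itself moves a probe up this scale. In 4 of the 11 higher probes the wild-type mean was already above 10 on the log2 scale. In 2 of them the wild-type mean was under 5.34, the 25th percentile of all probes, and close to 4.91, the log2 of the intensity offset of 30. Their folds may understate the change, but whether their wild-type signal lay above background was not examined. Over the 11 higher probes, the median difference was 2.05 on array 1, 1.83 on array 2, 2.37 on array 3 and 1.97 on array 4. The ages of the mice differed by 13 days on arrays 1 and 2 and by at most 1 day on arrays 3 and 4.

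**Figure D3:**
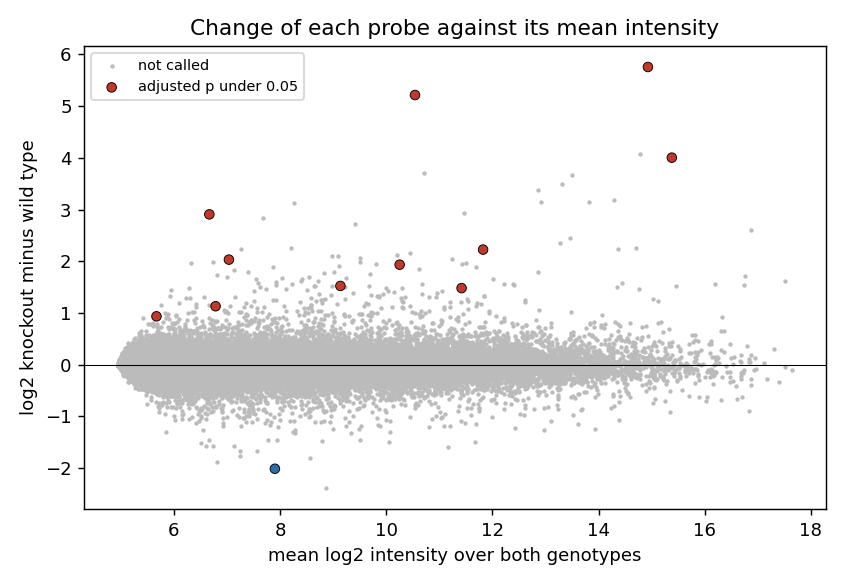
Knockout minus wild-type difference on the log2 scale (y axis) against mean log2 intensity (x axis) for 41174 probes; large points are those at an adjusted p under 0.05 (red, higher; blue, lower). The 11 higher probes all have a mean intensity above the 25th percentile, and the single lower probe changed by -2.02.

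**Figure D4:**
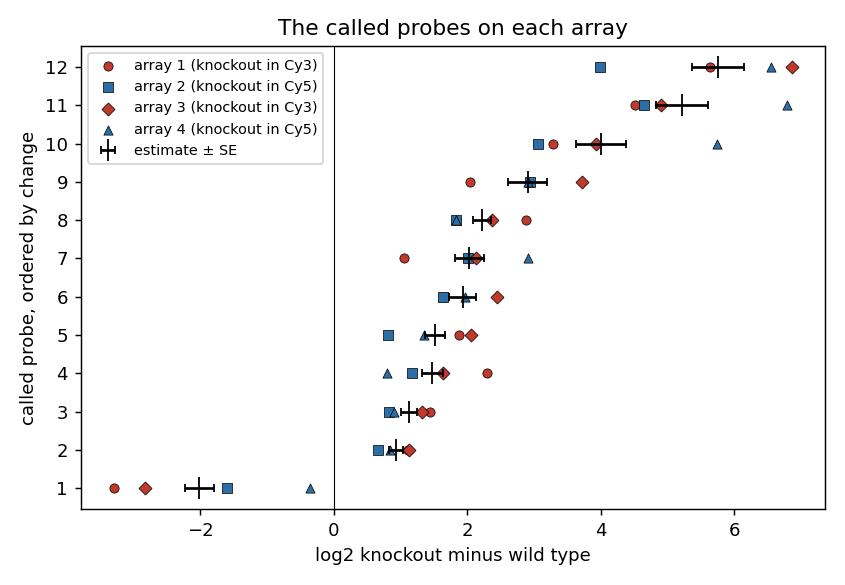
Knockout minus wild-type difference on the log2 scale (x axis) on each of the 4 arrays for the 12 called probes, ordered by size (y axis); black marks are the limma estimate ± SE. All 12 probes keep their sign on all 4 arrays, which follows from the lack of overlap between the genotypes. The largest rise ranges from 3.98 to 6.86.

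Few further probes differed by adjusted p, and the number at an unadjusted p under 0.05 depended on the samples included. An unadjusted p under 0.05 was reached by 2229 probes (5.41%), of which 1226 were higher and 1003 lower, against 2059 expected by chance. This number was 951 without knockout replicate 1 and 7792 without wild-type replicate 3, and between 1645 and 2983 without any other single sample. Without wild-type replicate 3 the correlation within arrays was estimated at 0.409 in place of 0.108. At an adjusted p under 0.1 in limma there were 16 higher probes and 1 lower, and at an adjusted p under 0.25 there were 38 and 5. The 4 knockout samples lay wholly above the 4 wild-type samples on 504 probes and wholly below on 362, where chance gives 588 (1.43%) in each direction. Of these separated probes, 97 were more than 2-fold higher and 12 more than 2-fold lower in the knockout.

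The number of called probes depended on which samples were included and on the treatment of the array. Leaving out knockout replicate 1 left 0 probes called by limma, with 951 at an unadjusted p under 0.05. Without knockout replicates 2, 3 or 4, 4, 4 and 2 probes were called higher, and without wild-type replicate 2, 3 were, all among the 11. Without wild-type replicate 3, 14 were called higher (8 among the 11) and 1 lower, and without wild-type replicate 4, 10 (4 among the 11) and 0. Without wild-type replicate 1, the sample that stood apart, 21 probes were called higher, among them all 11, and 1 lower. With the array as a fixed block, which leaves 2 residual degrees of freedom, limma called 0 probes, with 1620 at an unadjusted p under 0.05.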

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

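The tests of explanations in this part were chosen after the results were seen, except the test of a wrong genotype label. In 12 groups of 4 values (2 summaries per sample and 4 probes, in each genotype), 1 sample lay further from its group than Dixon's 95% criterion allows, and chance flags about 5% of groups. It was wild-type replicate 1, whose 4263 probes more than 2-fold from the median of the other samples compare with 282 to 703 in the other wild-type samples, a gap of 0.894 of the group's range.

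Several technical explanations for wild-type replicate 1 were argued against by the tables. A fault of array 1 that reached both channels would move knockout replicate 1 on the same spots. The deviations of the 2 samples from the median of the other 6, however, correlated at 0.018 across probes. The same correlation was 0.44, -0.028 and 0.075 on arrays 2, 3 and 4. Arrays 3 and 4 gave values near 0 although both of their samples stood apart together on a few probes. The value therefore argues only against a fault shared across many spots, not against a fault of few spots. Noise of dim probes near the background offset would leave the bright probes alike, but above the 75th percentile of intensity 1994 probes lay more than 2-fold from the median of the others, against 47 to 387 in the other 7 samples, or 5.15 times the highest of these. A knockout sample under a wild-type label would lie nearer 1 than 0 on a scale from the wild-type mean at 0 to the knockout mean at 1. On the 21 probes called higher without this sample its median position was 0.21, with 15 of the 21 under 0.5 and a range of -0.7 to 0.8. A bootstrap over these probes gave a 95% interval of -0.046 to 0.42, which measures the spread over probes within 1 sample and not between animals. The knockout samples chose these probes and set the end of the scale, so a knockout sample not used for the choice could lie below 1. A fault of its Cy5 channel alone, RNA quality and a different mix of tissue layers stay open and untested, since each needs gene names or scanner data.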

How the results depend on the processing

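The counts of called probes differed between the 27 alternatives. The 11 higher and 1 lower probes became 4 and 0 with no replicate block, 6 and 0 with no dye term, 2 and 0 with age as a covariate, and 24 and 2 with trended and robust moderation. With the array as a fixed replicate block, 0 and 0 probes were called by limma, both with the dye term (1620 at an unadjusted p under 0.05, smallest adjusted p 0.841) and without it (1277 and 0.515). The balanced design leaves the estimates the same under either block, and the fits had 2 and 3 residual degrees of freedom in place of 5. Leaving out 1 sample gave 0 to 21 higher and 0 to 1 lower, the lowest without knockout replicate 1 and the highest without wild-type replicate 1. Without wild-type replicates 3 and 4, 14 and 10 were called higher, with 8 and 4 of the 11 among them. Without knockout replicate 4 the 1 lower call was another probe. Leaving out both samples of an array gave 0 to 5 higher and 0 to 0 lower, with 0 without array 4 (2156 at an unadjusted p under 0.05). The number of probes at an unadjusted p under 0.05, 2229 with all samples, was 7792 without wild-type replicate 3, 7693 without array 3 and 3434 with sample weights, against 951 without knockout replicate 1 and 1426 with no dye term. Quantile normalisation, median centring, filters on dim probes and the series value table gave 8 to 11 higher probes, all among the 11, and 1 lower. Of the 27 alternatives, 4 were chosen after seeing the data. The authors' model with intraspotCorrelation gave 6 and 0, and sample weights gave 48 and 7 with all 12 among them. Leaving out wild-type replicate 1 and knockout replicate 4 gave 11 and 3 with 6 of the 11 shared. Removing 68 probes on which both samples of 1 array stood more than 2-fold apart from the other 6 gave 11 and 1. The intraspotCorrelation fit nearly repeated the fit with no dye term (smallest limma adjusted p 0.0069 in both, correlation within arrays -0.0204 and -0.0202). These 2 alternatives are therefore not separate checks, though both are counted among the 27. Probe A_51_P334930 lost its call in 6 of 27 alternatives, A_51_P314669 in 8 and A_52_P422494 in 16, while A_51_P307150 gained one in 4. The cause of these shifts was not tested. The replicate block is the array, since the labels share no replicate numbers between the genotypes. Changes of 1 on the log2 scale were recovered in only 50% of simulated probes, which limits what 4 samples per group can show. This share may be too high for these data, since the simulation had more changed probes and no sample that stood apart.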

Other observations

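The tests in this part were chosen after the results were seen, except the count over all splits. More of the larger differences were higher than lower in the knockout. Among probes on which the genotypes did not overlap, 97 were more than 2-fold higher in the knockout and 12 more than 2-fold lower. Of the 97, 60 lay above the 75th percentile of intensity of all probes, as did 5 of the 12. The intensity offset compresses differences between dim probes, so these shares do not show where changes were more frequent. Of the 250 probes with a mean log2 intensity above 15, 6 were separated and more than 2-fold higher, and 0 were separated and more than 2-fold lower. In 1 of the other 34 splits of the 8 samples as many probes (98) were separated and more than 2-fold apart in one direction. With both directions counted together the genotypes had 109, and 3 of the 35 splits, the genotypes included, had at least as many. The highest other split had 176. These counts alone therefore do not set the genotypes apart from other groupings.

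Of the 34 splits of the 8 samples that could be fitted, only the genotypes themselves gave as many as 12 calls. The highest other split gave 0. Most of these splits ignore that the samples were paired on arrays, so this count cannot exclude chance. Each array held 1 sample of each genotype, and the 7 splits that part all 4 arrays are too few for a share under 0.05: 1 of them gave 12 or more calls, the genotypes, and the highest other gave 0, while with the array as a fixed block limma called 0 probes (1620 at an unadjusted p under 0.05, smallest adjusted p 0.841). The 12 differences were not confined to arrays 1 and 2, where ages differed by 13 days. Their median size was 2.155 on arrays 3 and 4, where ages match within 1 day, against 2.045 on arrays 1 and 2. The median ratio was 1.27 and the lowest 0.652. A call over all 4 arrays favours probes with similar differences on each, so these ratios cannot decide whether age contributed. With age as a covariate the 12 estimates moved by at most 0.099 and their median standard error went from 0.207 to 0.224, but 2 of the 12 calls held with 4 residual degrees of freedom in place of 5, and since the 12 were called from all 4 arrays these values speak for no other probes. Loss of Runx1 in the epithelium stays open as the biological difference the design names, as do sequence variants near the transgene, which were not tested without gene positions. Both genotypes are labelled as floxed, so variants near the floxed gene are no labelled difference between them. The recombinase was present in the knockout mice only, so its presence cannot be told apart from loss of Runx1.

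On 15 probes both samples of 1 array stood more than 8-fold apart from all 6 other samples, 7 on array 2, 6 on array 3, 2 on array 4 and 0 on array 1. The 24 pairs of samples on different arrays held 0 such probes. Probe A_52_P587441, chosen after its values were seen, read 16.1 and 18.3 on array 4 and at most 5.83 in the other 6 samples. Of the 105 ways to pair the 8 samples, 1 held as many such probes, the real arrays (exact p = 0.0095), which is consistent with spots or hybridisation faults of single arrays. Age cannot be told apart from the array for arrays 3 and 4: the 2 pairs of equal age on different arrays held 0 such probes, but no other samples have the ages of arrays 3 and 4.

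Dye and genotype differed in how widely and how strongly probes were separated. The Cy3 and Cy5 samples did not overlap on 2804 probes, the most of any of the 35 splits, against 866 for the genotypes, a median of 1010 and 1176 expected by chance. Of the 2804 probes 85 were more than 2-fold apart, and of the 866 probes 109. The genotypes did not have the most of these: 3 of the 35 splits, the genotypes included, had at least 109, and the highest other had 176. In limma the dye term reached an unadjusted p under 0.05 on 5207 probes (12.6%) and an adjusted p under 0.05 on 0 (smallest 0.294), while genotype reached these on 2229 and 12 probes.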
